A study of Mus musculus with 4 samples.

How the data were processed

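Total RNA of 4 cultures of the MPC11 plasmacytoma line, 2 with a hairpin against GFP and 2 with a hairpin against Ell2, was sequenced on the SOLiD platform, per the labels' protocols. The authors deposited 1 table of read counts per gene symbol for each library, each naming 1 replicate, per the file headers. The values are whole numbers whose totals differ between libraries, so they were treated as raw counts. The submitters' processing notes name the mouse build mm9, SAMtools 0.1.11, HTSeq 0.5.3 and DESeq 1.4.1. The aligner, the gene annotation, the strand setting and any read filter are not given in the sources used here. Without a known strand setting, reads of a gene and of an antisense or overlapping partner could not be told apart. Of 47 genes named by the rules below or passing over a list alone, 15 overlap an exon of another gene in the GENCODE M21 annotation, among them Ell2 (an antisense transcript), Cp, Txndc5, Cstf2, Itga4 and Myl12b. That annotation and the RefSeq table are of build GRCm38, so no coordinates are given, and they served only for names, gene classes, sizes and which genes overlap.

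The 4 tables list the same 22722 genes, and none of their entries lacks a gene name. Of the symbols, 19239 matched the RefSeq table as written, 2216 through 1 older symbol and 1267 not at all; 1039 carry a suffix for a repeated copy of the gene. Library totals were 8323915 and 5088789 counts for shGFP replicates 1 and 2, and 13914488 and 3496471 for Ell2-KD replicates 1 and 2. The deepest and the shallowest library were both Ell2-KD, and the shallow library limits the precision for genes of low abundance.

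Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 11027, and libraries were scaled by TMM. The quasi-likelihood test (glmQLFit with robust settings, glmQLFTest, two-sided) compared Ell2-KD with shGFP over all 4 libraries with group as the only term, and p-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values, counts relative to the library total, are TMM-normalised, except where a share of all counts is given, and values after ± are SDs over 2 libraries unless marked SE. With 2 libraries per group the common biological coefficient of variation was 0.43. Correlations of log2 CPM between libraries ran from 0.87 to 0.92, so no 2 libraries were copies of one another.

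Before the data were examined, 27 gene lists were written for the depleted factor, the cell and common responses, among them markers of other cell types. Lists with at least 5 tested members, 22 in all, were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with the preset inter-gene correlation of 0.01, and adjusted over the lists. The 5 others (immunoglobulin genes and T cell, myeloid, erythroid and stromal markers) had 2 to 4 tested members; of the immunoglobulin list only Igj is reported. Counts of list members past the threshold are given over all genes and adjusted over the list alone. The second adjustment does not count the other lists searched in the same way. List medians are of edgeR log2 changes, except within a replicate number or after correction for length and GC, where they are of log2 CPM differences. At the preset correlation the camera p rests on the spread over genes. With a correlation estimated from the data it rests on the 2 residual degrees of freedom of the samples. Camera compares a list with all other genes, so its direction could differ from the sign of the median for lists near 0. It did so for B cell genes, elongation factors, p53 targets, ribosomal proteins and proteasome subunits.

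Genes named in the text were set before the data were examined: Ell2, Ell, Ell3, Hnrpll, Xbp1, Prdm1, Irf4, Hspa5, Cstf2 and Igj; up to 12 genes in each direction with the largest change among those past the threshold, with a mean of at least 5 CPM and no overlap between groups; up to 4 members with the smallest p of each list that held a gene past the threshold, or 2 of each list that passed camera alone; the 5 most abundant genes; and, since fewer than 10 genes passed, the 5 with the smallest p in each direction among those that did not. Of the genes this rule takes, 1 is not reported here.

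The test was tried on counts simulated from the real means, library sizes and trended dispersions, in 5 draws with 200 genes changed by known folds. Of 53964 unchanged genes, 22 were called. The plasma cell list, shifted by -1 on the log2 scale, was called lower in 5 of 5 draws, with 0 calls in 105 tests of other lists. Genes were drawn independently and with no effect of replicate number, so false list calls from correlated genes could not appear. The shift was larger than the observed median of -0.33, so these draws do not show the power for a change of that size. Alternatives were other scalings, filters and tests (DESeq2 1.42.0, limma-voom, edgeR's exact test), the replicate number as a block, each library left out in turn and, chosen after seeing the data, the small noncoding RNA genes (659 in the tables) left out and the plasma cell list without the members it shares with ER chaperones. Confidence intervals of shares are Wilson intervals (scipy 1.17.1).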

Results

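The RNA of 4 cultures of MPC11, a mouse plasmacytoma line that makes and secretes immunoglobulin, was counted gene by gene. Of these, 2 carried a lentiviral short hairpin RNA against Ell2 (Ell2-KD), which encodes a transcription elongation factor of RNA polymerase II, and 2 carried a hairpin against GFP, a sequence that mouse cells lack (shGFP, the control). Virus was removed after 18 h, puromycin selection lasted 72 h, and the cells were expanded for a further 72 h before RNA was taken. The labels call the samples of a group biological replicates without saying whether each was transduced separately, so edgeR p-values measure the spread between these samples. They also draw on variance information shared across genes. The camera p-values at the preset correlation rest on the spread over genes, not between samples. The libraries held 8323915 and 5088789 counts for shGFP replicates 1 and 2, and 13914488 and 3496471 for Ell2-KD replicates 1 and 2, over 22722 genes. Of these, 11027 genes had enough counts to be tested. The series was designed to examine splicing, but counts per gene do not separate isoforms, so the values describe total transcript levels and splicing was not analysed here.

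Ell2 itself was 9.53-fold lower in the depleted cells, and 4 other genes passed the test. Ell2 fell from 967 ± 41.2 CPM, normalised counts on a per-library scale (SD, n = 2), in shGFP to 102 ± 19.5 (SD, n = 2) in Ell2-KD, a log2 change of -3.25 ± 0.23 (SE; edgeR adjusted p = 0.00032), and the change was -3.41 within replicate number 1 and -3.11 within number 2. Its counts were 7864 and 5019 in the controls and 1238 and 394 in the depleted cells, and they can include reads of an antisense transcript that overlaps its exons. Tsc22d1, a leucine zipper transcription regulator, rose 3.66-fold, from 213 ± 18.4 to 778 ± 85.2 CPM (edgeR adjusted p = 0.017). Itih5, a heavy chain of the inter-alpha-trypsin inhibitor family, fell 5.25-fold, from 100.1 ± 8.76 to 19.1 ± 0.37 CPM. Ccnb2, which encodes the mitotic cyclin B2, fell 4.13-fold, from 181 ± 8.82 to 43.5 ± 7.34 CPM. Trp53inp1, a p53-induced stress protein that is also abundant in plasma cells, fell 3.25-fold, from 1154 ± 245 to 355 ± 47.4 CPM. Each of these last 3 genes had an edgeR adjusted p of 0.043. All 4 changes were of similar size within each replicate number: 1.84 and 1.89 for Tsc22d1, -2.48 and -2.27 for Itih5, -1.83 and -2.28 for Ccnb2, and -1.77 and -1.61 for Trp53inp1, on the log2 scale. The genes were called from these same libraries, so this likeness is no separate evidence.

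**Figure D1:**
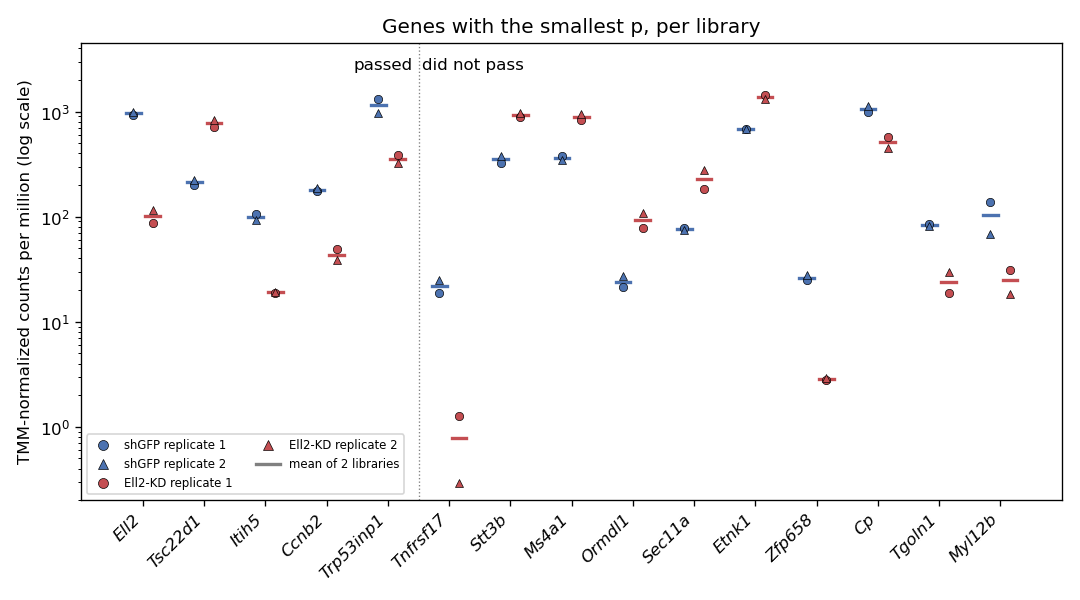
TMM-normalised CPM (log axis) in each of the 4 libraries for the 5 genes that passed the test (left of the dotted line) and 10 genes that did not pass, the 5 higher and 5 lower with the smallest p among those. Circles are replicate 1, triangles replicate 2, blue shGFP, red Ell2-KD and horizontal bars the mean of 2 libraries. Ell2 lies at 938 and 996 CPM in the controls and at 87.8 and 115 CPM in the depleted cells.

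The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested. At an unadjusted p under 0.05 it gave 642 genes, 283 higher and 359 lower, where 0.05 of the tested genes is about 551. That number is no firm measure of chance in this design. The same test gave 1011 genes between replicates 1 and replicates 2. It gave 110 with shGFP replicate 1 and Ell2-KD replicate 2 set against the other libraries. In counts simulated at this depth and spread, it called 6.01% of genes changed 2-fold, 51.2% of those changed 4-fold and 76.6% of those changed 8-fold, so changes of about 2-fold were mostly not detectable with 2 libraries per group. Ell2 passed whichever library was left out, while of the 5 genes it alone passed without shGFP replicate 1 or without Ell2-KD replicate 2, 2 passed without Ell2-KD replicate 1 (with Tsc22d1) and 3 without shGFP replicate 2 (with Tsc22d1 and Trp53inp1).

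The 5 genes with the smallest p in each direction among the others did not pass in this fit, which had group as its only term. Their calls with the replicate number as a block are given below. Both depleted libraries lay on the same side of both controls for each of them. This adds no support, since a small p in these libraries selects for it. Such a separation held for 35.8% of all tested genes, where chance alone would give 33.3%. Toward higher levels, Stt3b, a catalytic subunit of the oligosaccharyltransferase that glycosylates proteins in the endoplasmic reticulum (ER), stood at 934 ± 51.9 CPM in depleted cells against 351 ± 41.2 in controls (edgeR adjusted p = 0.052). The call for Stt3b changed with the scaling, filter and test, as given below. Ms4a1, the B cell antigen CD20, stood at 888.5 ± 74.1 against 363 ± 21.4 CPM (edgeR adjusted p = 0.086). Ormdl1, a regulator of sphingolipid synthesis, had a log2 change of 1.96 ± 0.35 (SE), Sec11a, a catalytic subunit of the signal peptidase, 1.59 ± 0.28, and Etnk1, an ethanolamine kinase, 1.01 ± 0.19, with edgeR adjusted p of 0.183, 0.183 and 0.225. Toward lower levels, Tnfrsf17, the plasma cell survival receptor BCMA, had 159 and 126 counts in the controls and 18 and 1 in the depleted cells (edgeR adjusted p = 0.18). Zfp658, a zinc finger gene, stood at 2.85 ± 0.11 against 26.4 ± 1.71 CPM. Cp, which encodes ceruloplasmin, had a log2 change of -1.05 ± 0.21, Tgoln1, a trans-Golgi network protein, -1.79 ± 0.36, and Myl12b, a myosin regulatory light chain, -2.05 ± 0.42. For these last 4 genes the edgeR adjusted p lay between 0.225 and 0.293. Myl12b overlaps exons of its close relative Myl12a, so its value is uncertain.

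Genes of plasma cell identity were lower as a group in the depleted cells. Of 35 tested members of this list, 31 had a negative and 4 a positive log2 change, with a median of -0.33 (camera, adjusted p = 0.0019, and 0.62 with an estimated correlation). In the log2 CPM that camera tested the median was -0.29. Over all genes tested, 1 member fell (Trp53inp1) and none rose. Adjusted over the list alone, which does not count the other lists, 7 members fell and none rose. Apart from Trp53inp1, their edgeR adjusted p over all genes ran from 0.18 (Tnfrsf17) to 0.58 (Sdc1). These were Trp53inp1, Tnfrsf17, Tnfrsf13b, Fkbp11, Pou2af1, Itga4 and Sdc1, of which the last 3 are named after their values were seen. Tnfrsf13b, the receptor TACI, fell from 136 ± 33.5 to 53.3 ± 9.11 CPM (edgeR, p adjusted over the list alone 0.013), and Fkbp11, an ER prolyl isomerase, from 75.9 ± 0.19 to 26.6 ± 7.77 CPM (0.013). Pou2af1, the coactivator of octamer-binding factors at immunoglobulin promoters, fell from 1015 ± 156 to 549 ± 103 CPM (edgeR, 0.014). Itga4, the alpha 4 integrin, fell from 81.0 ± 33.2 to 28.4 ± 10.8 CPM and Sdc1, the plasma cell surface proteoglycan CD138, from 716 ± 96.0 to 413 ± 92.1 CPM.

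The transcription factors at the head of the plasma cell programme did not pass. Prdm1 (Blimp-1) had a log2 change of -0.39 ± 0.24 (SE), Irf4 of -0.28 ± 0.20 and Xbp1 of -0.05 ± 0.42. With 1 library left out Prdm1 ranged from -0.59 to -0.13 (without shGFP replicate 1) and Irf4 from -0.46 to -0.11 (without Ell2-KD replicate 2). Xbp1 varied more between replicate numbers than between groups, at 4229 and 2224 CPM in the controls and 3971 and 2251 CPM in the depleted cells. Of 24 immunoglobulin and J chain genes looked for by name, 5 were among the genes counted and 2 were tested. Immunoglobulin transcripts as a group were therefore not assessed. Igj, the joining chain of polymeric immunoglobulin, was one of the 5 tested genes with the highest mean CPM. It stood at 8842 ± 542 against 10779 ± 1329 CPM in controls (log2 change -0.29 ± 0.16, and -0.41 to -0.14 with 1 library left out). The list's median was -0.23 within replicate number 1 and -0.32 within number 2, and the list passed camera whichever library was left out (adjusted p = 0.00786 to 0.0496). Without the 5 members shared with the ER chaperone list below, the camera adjusted p was 0.0094.

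B cell genes that plasma cells normally silence moved in both directions. Of 30 tested members, 14 had a positive and 16 a negative log2 change, and the list did not pass (camera, adjusted p = 0.52); its test pointed up while its median, -0.03 (0.14 within number 1 and -0.16 within number 2), and its mean, -0.09, lay just below 0. The median was 0.23 under a stricter filter, 0.24 without shGFP replicate 2, 0.12 without Ell2-KD replicate 2, 0.04 without shGFP replicate 1 and -0.09 without Ell2-KD replicate 1, and the list passed in none of these. No member passed over all genes in the main fit, though Ms4a1, Cd24a, Irf8 and Vpreb3 each did in some alternative. Adjusted over the list alone, 3 rose and 1 fell. Ms4a1 rose (values above), Cd24a, the surface glycoprotein CD24, rose from 31.9 ± 4.60 to 105 ± 26.1 CPM and Vpreb3, a pre-B cell protein, from 3.28 ± 2.11 to 22.9 ± 6.52 CPM. Irf8, a transcription factor of B and myeloid cells, fell from 93 and 37 counts in the controls to 3 and 0 in the depleted cells. Cd24a, Vpreb3, Irf8, Cd79b and, below, Itga2b are named after their values were seen. Cd79b, a B cell receptor chain, had a log2 change of -0.04 ± 0.19. Markers of other cell types were scarce. Summed over 26 myeloid genes they made up 43.2 and 32.6 CPM of all counts in the controls and 44.1 and 61.2 in the depleted cells, over 23 T and NK cell genes 29.2 and 26.1 against 18.3 and 23.7, and over 19 fibroblast and epithelial genes 9.61 and 21.8 against 14.1 and 35.5. The 12 erythroid and megakaryocyte genes summed to 8.77 and 6.88 against 19.1 and 32.6, most of it in the depleted cells from the integrin gene Itga2b.

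ER chaperones and quality control genes were lower as a list. Of 40 tested members, 33 had a negative and 7 a positive change, with a median of -0.23 on the log2 scale, -0.35 within number 1 and -0.16 within number 2 (camera, adjusted p = 0.027; adjusted p = 0.62 with an estimated correlation). No member passed over all genes. Adjusted over the list alone, Txndc5, a disulfide isomerase, fell from 2113 ± 17.8 to 1224 ± 163 CPM, and Fkbp11 fell as given above. Hspa5, the ER chaperone BiP, stood at 3616 ± 88.0 against 4272 ± 143 CPM in controls (log2 change -0.24 ± 0.16), and Hsp90b1, the chaperone GRP94, at 5790 ± 951 against 7612 ± 1951 CPM; neither passed. The list passed without shGFP replicate 2 (camera, adjusted p = 0.0203) but not without shGFP replicate 1 (median -0.11; 0.168), Ell2-KD replicate 1 (0.238) or Ell2-KD replicate 2 (0.118).

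The machinery of ER translocation and vesicle transport did not pass as a list, with 40 of 60 members negative and a median of -0.18 (camera, adjusted p = 0.25). Adjusted over the list alone, Stt3b and Sec11a rose and no member fell. Targets of ATF4 and CHOP in the integrated stress response, with 25 of 35 members negative and a median of -0.23, did not pass (camera, adjusted p = 0.081), and neither did cytosolic heat shock genes, with a median of 0.11 (camera, adjusted p = 0.26). With 1 library left out these medians ranged from -0.31 to -0.06 (without Ell2-KD replicate 2) and from 0.10 to 0.26 (without shGFP replicate 1).

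Genes of cholesterol synthesis and uptake were lower as a list. Of 33 tested members, 21 had a negative and 12 a positive change, with a median of -0.47 (camera, adjusted p = 0.031, and 0.62 with an estimated correlation). In the log2 CPM that camera tested the median was -0.29, with -0.16 within number 1 and -0.56 within number 2. No member passed, over all genes or adjusted over the list alone. Pmvk, a kinase of the mevalonate pathway, stood at 5.21 ± 1.75 against 23.1 ± 0.70 CPM in controls. The list passed without Ell2-KD replicate 1 (camera, adjusted p = 0.00481) but not without shGFP replicate 1 (0.0545), shGFP replicate 2 (0.165) or Ell2-KD replicate 2 (median -0.22; 0.385).

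Replication-dependent histone genes were also lower as a list, though not within replicate number 1. Of 53 tested members, 43 had a negative change, with a median of -0.32 (camera, adjusted p = 0.031; adjusted p = 0.72 with an estimated correlation), and no member passed, over all genes or adjusted over the list alone. The 2 members with the smallest p were Hist1h2ak, at 18.1 ± 0.77 against 44.3 ± 13.1 CPM in controls, and Hist2h4, at 95.6 ± 7.26 against 166 ± 36.4 CPM. Histone genes took 0.57% and 0.97% of counts in shGFP replicates 1 and 2 and 0.53% and 0.65% in Ell2-KD replicates 1 and 2. The median was -0.02 within number 1 and -0.64 within number 2. The list passed without shGFP replicate 1 (median -0.64) but not without Ell2-KD replicate 1 (-0.28; camera adjusted p = 0.325) or Ell2-KD replicate 2 (-0.54; 0.106), and without shGFP replicate 2 its median was 0.14 (0.571).

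Lists of factors that act in elongation, 3' end formation and splicing did not pass. Of 43 elongation factors, 20 had a positive and 23 a negative change, with a median of -0.00 (camera, adjusted p = 0.74). The paralogs of Ell2 did not pass: Ell stood at 21.8 ± 11.4 against 18.8 ± 6.83 CPM in controls, and Ell3 had 48 and 17 counts in the controls and 77 and 0 in the depleted cells. Among 26 cleavage and polyadenylation factors the median was 0.17 (camera, adjusted p = 0.26), and 0.06 without Ell2-KD replicate 2. Cstf2, the 64-kDa cleavage stimulation factor subunit that has been tied to secretory immunoglobulin polyadenylation, stood at 472 ± 47.9 against 313 ± 78.7 CPM (log2 change 0.59 ± 0.24, and 0.36 to 0.89 with 1 library left out; edgeR adjusted p = 0.81). Among 46 hnRNP and SR splicing regulators, 34 had a positive change, with a median of 0.11 (camera, adjusted p = 0.081). Hnrpll, a splicing regulator of plasma cells, stood at 142 ± 29.8 against 134 ± 31.3 CPM, with a log2 change of 0.09 ± 0.28 whose 95% confidence interval ran from -0.54 to 0.71.

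Cell cycle genes did not pass as lists. Of 46 G2/M genes, 31 had a negative change with a median of -0.09 (camera, adjusted p = 0.29), and Ccnb2 was the only member to pass, over all genes and over the list alone. The members next in order, Mki67 with a log2 change of -0.45 ± 0.18, Ckap2l with -0.72 ± 0.31 and Cenpa with -0.84 ± 0.40, did not pass, and with 1 library left out Mki67 ranged from -0.58 to -0.30 and Cenpa from -1.35 to -0.34. The 50 G1/S genes had a median of 0.04 (camera, adjusted p = 0.44). Among 37 p53 targets and apoptosis regulators, 18 were positive and 19 negative (camera, adjusted p = 0.70), and Trp53inp1 alone passed. Bcl2, an inhibitor of apoptosis, stood at 31.6 ± 2.48 against 11.1 ± 1.48 CPM, its relative Bcl2l1 at 155 ± 6.45 against 95.8 ± 14.0 CPM, and the stress gene Gadd45b at 71.5 ± 19.1 against 147 ± 13.5 CPM, none of which passed. No member passed and the list did not pass for NF-kappaB targets (median 0.22; camera adjusted p = 0.061, and 0.0398 after correction for transcript length and GC content), glycolysis and hypoxia genes (-0.23; 0.071), interferon-stimulated genes (0.18, with 0.24 within number 1 and -0.17 within number 2; 0.30), ribosome biogenesis and MYC-responsive genes (0.05; 0.26), autophagy and lysosome genes (0.06; 0.26), respiratory chain subunits (-0.04; 0.91), ribosomal proteins (-0.05; 0.80) and proteasome subunits (-0.02; 0.91). With 1 library left out the median ranged from -0.0009 (without Ell2-KD replicate 1) to 0.25 for interferon-stimulated genes, from -0.07 to 0.07 for p53 targets and from -0.05 to 0.12 for ribosome biogenesis genes.

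**Figure D2:**
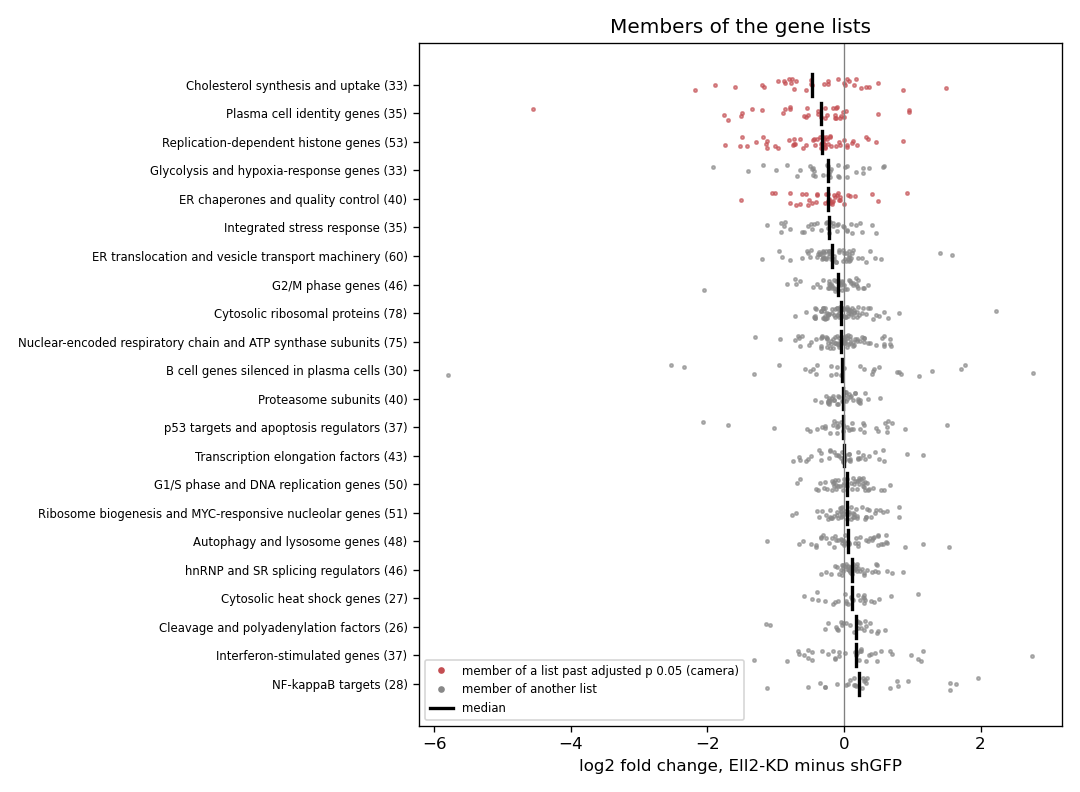
Log2 fold change (Ell2-KD minus shGFP) of each tested member of the 22 gene lists, with the number of members in parentheses. Each point is a gene, black bars are medians, and red marks the 4 lists past a camera adjusted p of 0.05, whose medians run from -0.23 for ER chaperones to -0.47 for cholesterol genes.

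The libraries also differed by replicate number. Small noncoding RNAs, mostly small nucleolar RNAs, took 0.35% of counts in shGFP replicate 1 (95% Wilson interval 0.347% to 0.355%) and 0.31% in Ell2-KD replicate 1, but 3.03% and 2.62% in replicates 2 (3.01% to 3.04% and 2.60% to 2.64%). These intervals cover counting error only. The U1 small nuclear RNA gene Rnu1b2, chosen after its values were seen, had 317 and 397 counts in replicates 1 of shGFP and Ell2-KD and 15707 and 8133 in replicates 2. Of the tested genes with the highest mean CPM, the noncoding RNA Malat1 stood at 12179 ± 2409 against 10291 ± 1362 CPM. Lars2, the mitochondrial leucyl-tRNA synthetase gene, stood at 4359 and 13336 CPM in the depleted cells against 7660 and 8771 CPM. Neither Malat1 nor Lars2 passed.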

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

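Leaving out small noncoding RNA genes, and leaving out the plasma cell members shared with the ER chaperone list, were chosen after seeing the data; the other settings were planned. Ell2 kept its direction and its call in all 17 alternatives run for it, with log2 changes from -3.46 to -3.06. The count of 5 changed genes was 4 to 7 with DESeq2 size factors, upper-quartile scaling, a stricter filter, limma-voom (4, without Ccnb2 and Itih5), the 10 most abundant genes or small RNAs left out, or an adjusted p under 0.10. It was 2 with library totals alone and 2 against a fold of 1.2 (Ell2 and Tsc22d1 in both), 1 without robust settings, 17 with edgeR's exact test, 22 with no filter and 43 with DESeq2's Wald test, where 428 adjusted p were NA; the cause was not tested. All 5 genes were among the 17, the 22 and the 43, and so were Tnfrsf17 and Cd24a. Ms4a1 was among the 22 and the 43, and Irf8 among the 17 and the 43. Tnfrsf13b, Fkbp11 and Vpreb3 were among the 43 alone, and Pou2af1, Itga4 and Sdc1 in none of them. With each library left out in turn the count ranged from 1 to 6, with fewer samples behind each fit and the lone sample of a group assumed to vary like the other group. The replicate numbers are not stated to mark a shared culture or day. Across genes, the deviations of same-numbered libraries from their group means correlated at r = 0.31, and the replicate block raised the count to 28, 15 higher and 13 lower, with all 5 genes kept. At an unadjusted p under 0.05 the block gave 1168 genes. Of the 10 genes with the smallest p, 5 in each direction, among those that did not pass, 8 were among the 28, with edgeR adjusted p from 0.00321 (Stt3b) to 0.0443 (Tgoln1): Stt3b, Ms4a1, Ormdl1, Sec11a, Etnk1, Cp, Tgoln1 and Myl12b, but not Tnfrsf17 or Zfp658. Also among the 28 were Pou2af1 (edgeR adjusted p = 0.0356) and Cd24a (0.0330), but not Tnfrsf13b, Fkbp11, Itga4, Sdc1, Irf8 or Vpreb3. Dok7, picked after its values were seen, was among the 28 too. It rested on shGFP replicate 2, at 119 CPM against 0.12 in shGFP replicate 1. Of the lists, 4 passed, against 0 with an estimated inter-gene correlation, 0 with fry, which tests each list on its own, 5 with the block, which added glycolysis and hypoxia genes and moved the cholesterol median from -0.47 to -0.28, and 1 to 3 with a library left out, where splicing regulators passed as higher without shGFP replicate 1 (camera adjusted p = 0.0482) and ribosomal proteins without shGFP replicate 2 (0.0321). The plasma cell list passed in each alternative run except the estimated correlation (unadjusted p = 0.058) and fry (unadjusted p = 0.0114, adjusted 0.232). Genes near 0 changed sign: Ell was -0.0627 with limma-voom and ranged from -0.45 to 0.68 with a library left out, Ell3 from -7.69 to 0.25, Hnrpll from -0.14 to 0.35 and Xbp1 from -0.52 to 0.50, with 0.0130 under no filter and 0.0155 under limma-voom. Lars2 was -0.23 with limma-voom, -0.10 with the block and -0.91 to 0.71 with a library left out. Among lists, the direction of camera turned with a library left out for histones (medians -0.64 to 0.14), G1/S genes (-0.0694 to 0.15), respiratory chain subunits (-0.19 to 0.0782), ribosomal proteins (-0.23 to 0.31) and proteasome subunits (-0.0553 to 0.0419). It also turned under the stricter filter for respiratory chain subunits (-0.0258) and ribosomal proteins (-0.0567), and fry's direction differed for ribosomal proteins (-0.0476) and proteasome subunits (-0.0216). No scaling run moved the median of all genes by over 0.1. The shallowest library, Ell2-KD replicate 2, limits the precision for genes of low abundance.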

Other observations

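Among the tests below, library depth, the share of plasma-type cells and the hairpin were chosen after the result was seen. Stt3b and its paralog Stt3a, the alternative catalytic subunits of the oligosaccharyltransferase, differed in their values. Stt3b stood at 898 and 971 CPM in the depleted cells against 322 and 380 in the controls, while Stt3a stood at 1336 and 1274 against 1211 and 1297 CPM (log2 change 0.06 ± 0.18, SE). Stt3b and Sec11a, which passed over the list alone, were higher in a list of secretory machinery whose median was -0.18. The difference between the paralogs was not tested, and Stt3a was picked after its values were seen.

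The lower level of plasma cell identity genes, from surface proteins (Tnfrsf17, Tnfrsf13b, Sdc1) to Pou2af1, is the pattern most worth following up. In the main fit these genes passed when adjusted over the list alone but not over all genes. The list did not pass with camera at an estimated correlation (adjusted p = 0.616) or with fry (adjusted p = 0.232). Its estimated correlation was 0.0090, below the preset 0.01, so correlation among its members was not what raised the camera p. The values argue against library depth as the whole cause, since the depleted library was 1.67 times as deep as its control in number 1 and 0.69 times in number 2, yet the list's median was below 0 in both, at -0.23 (95% bootstrap interval -0.66 to -0.14) and -0.32 (-0.60 to -0.09), with 1 library on each side and intervals that cover the spread over list members, not between samples. After the trends with transcript length and GC content were removed from each library, the median in log2 CPM moved from -0.29 to -0.33 (-0.58 to -0.16, camera adjusted p = 0.00361). A lower share of plasma-type cells in the culture would raise B cell markers alike. The 30 tested B cell genes did not rise together, with 14 positive, 16 negative and a median log2 change of -0.03. That median was 0.14 within number 1, -0.16 within number 2 and 0.23 under a stricter filter. Of the B cell genes that passed over the list alone, 3 rose and 1, Irf8, fell, and 1 gene of low abundance decides nothing. These values point both ways, so this explanation stays open, as does a change in the type of the cells themselves. Only 1 hairpin against Ell2 was used, so an off-target effect of the hairpin cannot be told apart from ELL2 depletion, and the direct or indirect action of ELL2 on these genes remains an untested hypothesis.

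Small noncoding RNAs were several-fold higher in the replicate 2 libraries of both groups. Across 123 tested small RNA genes the median change from replicate 1 to replicate 2 was 2.78 in shGFP and 2.47 in Ell2-KD on the log2 scale, and 106 of them were higher in each. Higher expression of the host genes argues poorly: the 56 protein-coding genes that hold 70 of them had medians of 0.01 and 0.07 (upper bootstrap bounds 0.19 and 0.21). The difference between small RNA and host was 3.34 in shGFP and 2.69 in Ell2-KD, consistent with a different recovery of short RNA in the library; a biological difference between the cultures of the 2 numbers was not tested. The 85 small nucleolar RNAs showed the largest medians (3.34 and 3.03), while the 21 microRNA genes showed 0.33 and -1.53.

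The 4 libraries can be split into pairs in 3 ways. The real split gave 5 genes, and the split by replicate number gave 93, of which 55 were small noncoding RNA genes. The crossed split gave 0 (110 at an unadjusted edgeR p under 0.05). Counting the real split itself, 2 of the 3 splits gave at least 5 genes. With 3 splits no share under 0.05 can be had. The 93 genes point to a structure of the samples by replicate number.

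A loss of an elongation factor might lower long genes more than short ones. This hypothesis was tested across 10592 protein-coding genes, which are not independent replicates, and the values did not bear it out in both numbers: Spearman's rho of the log2 change with genomic length was -0.0349 within number 1 and 0.0796 within number 2. Genes over 100 kb had a median change of -0.01 and genes under 10 kb one of -0.06; these were -0.06 and 0.03 within number 1, and -0.01 and -0.14 within number 2.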
